A study of Mus musculus with 28 samples.

How the data were processed

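RNA from whole-lung homogenates of male C57BL/6 mice, an inbred laboratory strain, was sequenced as stranded paired-end mRNA libraries. The 28 libraries form 8 groups by exposure and day. The exposures were sham, carbon black (a particle of nearly pure carbon) at 10 mg/m3, ozone (an oxidant gas) at 2 ppm, and co-exposure to both, each lasting 3 hours. Day 1 groups received 1 exposure and hold 4 libraries each, and day 4 groups received 4 exposures and hold 3 libraries each. The time from the last exposure to lung collection is not given in the sources used here. Every library was put in its group by its title, which also gives its replicate number. The labels do not state that each library came from its own mouse, so p-values measure the spread between these libraries, and day and number of exposures cannot be separated.

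Per the labels, the authors mapped and quantified the reads with Salmon 1.1.0, and the submitters' processing notes name the mouse genome build mm10, R 3.6.3 and DESeq2 without giving their roles. The deposited table holds estimated counts per gene that were not normalized, with 17.7% of the values not whole. They were rounded to whole numbers here. Salmon divides reads that match several transcripts by an estimate, so values of near-identical genes, such as hemoglobin genes, Hspa1a and Hspa1b, immunoglobulin segments, the Sprr2 family and pseudogenes, are uncertain. How transcripts were summed to genes and whether length or GC corrections were switched on is not given in the sources used here. Selection of mRNA leaves out most RNA without a poly(A) tail, and a homogenate gives the average over all cells of the lung, so a change in a gene's level and a change in the share of cells that express it look alike.

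The table has 35880 Ensembl gene identifiers, of which 11803 had no count in any library. Symbols and positions came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, which held 35434 of the identifiers and left 446 unnamed. Coordinates are 1-based. Totals ran from 5.14 M to 9.72 M estimated counts per library (M, mega), with a median of 7.19 M. A gene with no count in a library could lie anywhere under 3 counts, a limit of 0.309 to 0.584 CPM depending on the library. Intervals and floors of this kind cover counting error only. Where all libraries of the lower group had no count, a fold is given as a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with a 95% counting interval.

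Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion estimation on the rounded counts. Counts were scaled with TMM factors, which lay between 0.902 and 1.05, and low genes were removed with filterByExpr, which left 14887 genes and 99.9% of all counts. All 28 libraries entered a single fit with a mean per group and no covariate, which gave 20 residual degrees of freedom and a common biological coefficient of variation of 15.7%. The 16 comparisons comprised each exposure against sham of its day, co-exposure against each single exposure, the interaction of the exposures on the log scale at each day, the difference of each exposure's change between days, and sham of day 4 against sham of day 1. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and fold changes are on the log2 scale with standard errors (SE). Levels are TMM-normalized CPM, counts scaled to a common library total, with the standard deviation (SD) over libraries. The scaling left the median log2 fold change of all genes between -0.01 and 0.01 in each comparison.

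Before the data were examined, 34 lists holding 471 genes of pathways, lung cell types and neighbouring tissues were fixed, along with the comparisons, the alternatives and the rule for named genes. Each list was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison. The estimated correlation and fry are alternatives. Members past the threshold were counted over all genes tested and, separately, adjusted over the list alone. Named genes were taken from, for each exposure against sham, the 10 with the largest rise and the 6 with the largest fall among those past the threshold, changed by at least 1 on the log2 scale, without overlap of the libraries, at 2 CPM or more in the higher group and with a curated symbol. In other comparisons the numbers were 6 and 4, and overlap was not required where more than 2 groups entered. Up to 4 members of each list with the smallest p, and a set of 17 fixed genes, were added. The fixed genes Cxcl1 and Il6 were removed by the low-count filter and were not tested. Outside this rule, S100a8 against sham, Ltf, the levels of Retnla and Kdr where the rule did not name them, and Acta1, Ucp1 and Myh6 by library were chosen after their values were seen.

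The alternatives were median-of-ratios scaling, no low-count filter, a stricter filter at a mean of 1 CPM, limma-voom, DESeq2 1.42.0, a fit with the compared groups only, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a fit without the robust option, leave-outs for the lists, removal of each library's trends with exonic length and transcript GC content, and a combination of that removal with 1 library left out. Deviations from the group means correlated above 0.1 in all 3 same-numbered pairs of libraries, each best with its own number, only between sham and co-exposure at day 4 (0.35, 0.15 and 0.25). The labels do not say what a replicate number shares. Exonic lengths were known for 99.8% of the tested genes. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.24 in every pair.

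The test was checked on simulated counts for 14728 genes with 200 changed genes. For co-exposure against sham at day 1 it recovered 76% of genes changed by 1 on the log2 scale and 95% of those changed by 2, and called 9 unchanged genes. For the day 4 interaction it recovered 51% and 85%. In the simulated co-exposure against sham at day 1, camera called none of 40 unchanged lists and called the planted list. The simulated genes varied independently of each other, so this does not test the preset inter-gene correlation in the real libraries. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the table, and matplotlib 3.10.9 drew the plots.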

Results

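Messenger RNA was measured in lung homogenates of mice that breathed sham air, carbon black, ozone, or both, after 1 exposure (day 1, 4 libraries per group) or 4 exposures (day 4, 3 libraries per group). Ozone at 2 ppm and carbon black at 10 mg/m3 were given for 3 hours at a time. Each library held between 5.14 M and 9.72 M estimated counts. Within groups, log2 CPM values of library pairs had Pearson correlations across genes from 0.943 to 0.985. The first principal component took 25.8% of the variance and placed the day 4 ozone and co-exposure libraries between 33.5 and 64, against -34.6 to -17.2 for all sham and carbon black libraries. The second component took 13.7%.

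Fewer genes passed the threshold after carbon black than after ozone, and the carbon black counts depended strongly on the fit. At day 1, 247 genes passed the threshold after carbon black, 1704 after ozone and 2854 after co-exposure. At day 4 the counts were 31, 3089 and 5073. Carbon black gave 7 genes at each day with only the compared groups in the fit, and 653 at day 4 without carbon black replicate 3. At day 4 of carbon black 2266 genes had an unadjusted p under 0.05 in edgeR, where 744 would by chance. No gene passed between the sham groups of the 2 days in edgeR, DESeq2 or limma-voom, with 1473 genes at an unadjusted p under 0.05 in edgeR. With only the compared groups in the edgeR fit, these unadjusted counts were 1192 for carbon black at day 4 and 2106 between the sham groups. The excess at day 4 of carbon black thus depends on the fit, and an excess also arose between groups without exposure.

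**Figure D1:**
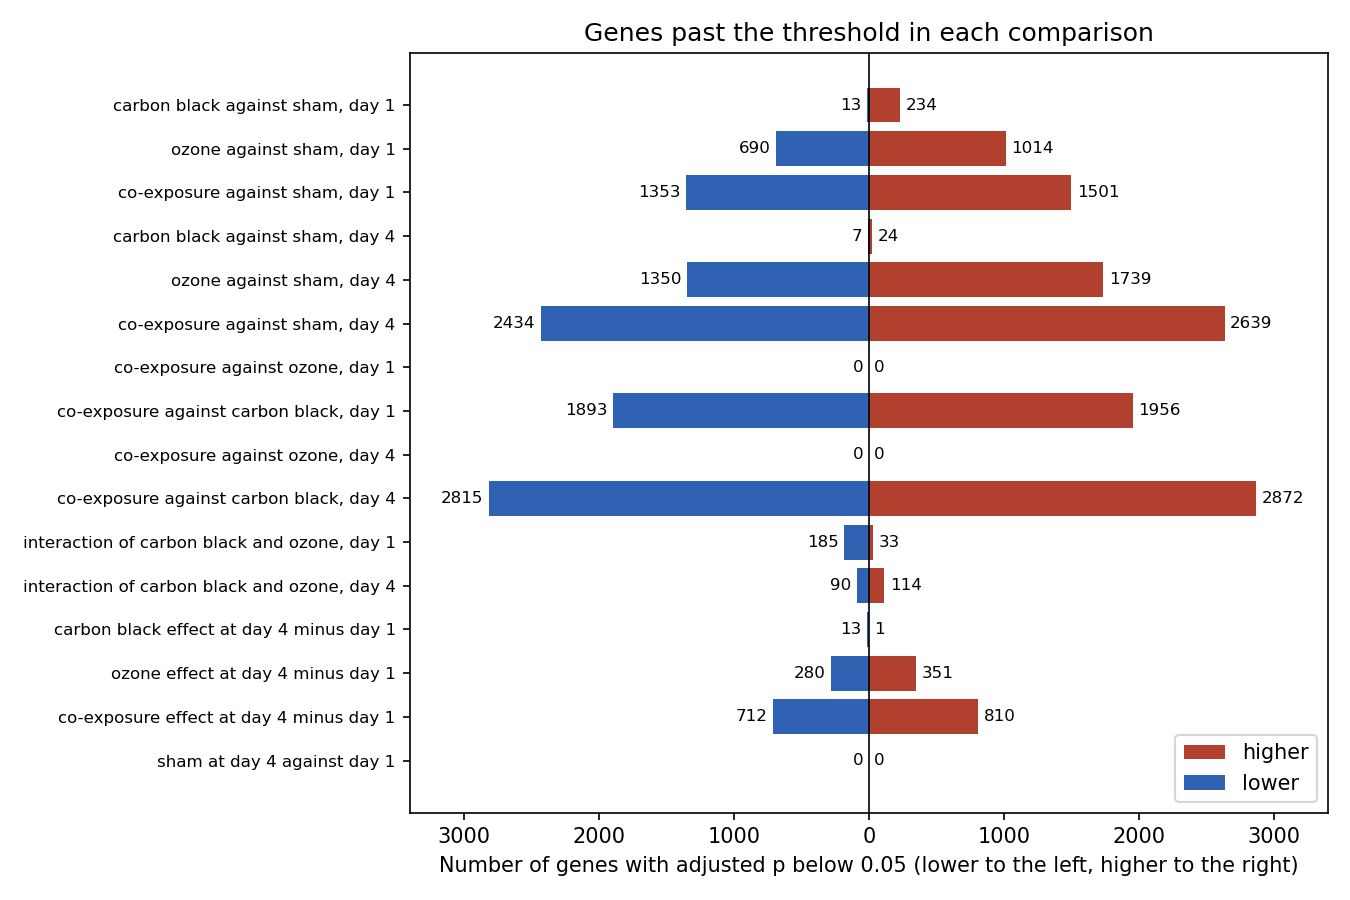
Number of genes past the adjusted p threshold of 0.05 in each of the 16 comparisons, drawn to the right for higher genes and to the left for lower genes. Carbon black alone gave 247 genes at day 1 and 31 at day 4, against 1704 and 3089 for ozone and 2854 and 5073 for co-exposure.

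The comparison of carbon black with sham at day 1 asked what a single inhalation of the particle changed. Genes of neutrophils, the granulocytes that enter tissue early in inflammation, rose. Of 13 tested neutrophil genes 12 rose, also 12 adjusted over the list alone, with a median log2 fold change of 4.01 (camera adjusted p = 2.35e-25, and adjusted p = 0.0306 with an estimated correlation). S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), which encodes a calcium-binding protein abundant in neutrophils, stood at 24.5 ± 22 CPM in sham and 598 ± 580 CPM after carbon black (SD, n = 4 each). Its log2 fold change was 4.62 ± 0.80 (SE). Retnlg rose by 4.86 ± 0.78, the decoy receptor gene Il1r2 by 4.01 ± 0.67, the gelatinase gene Mmp9 by 3.39 ± 0.57 and Clec4d by 2.92 ± 0.43. The granule protein gene Ngp (5.28 ± 1.1) and the interleukin 8 receptor gene Cxcr1 (2.47 ± 0.44) rose as well, as did Cd177 (2.43 ± 0.44), Mgam (2.91 ± 0.54), Wfdc17 (2.55 ± 0.40) and Trpm2 (2.37 ± 0.41). Mrgpra2b had 1 count in all sham libraries and 183 counts after carbon black, a ratio of 181 with a counting interval of 32.1 to 7200. The granule gene Ltf was the member that did not pass, at -0.63 ± 0.62.

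Carbon black replicate 2 did not share this rise, with S100a8 at 28 CPM against a sham maximum of 57.1 CPM. Its mean log2 CPM over the neutrophil genes was 3.02, inside the sham range of 2.08 to 3.29, while replicates 1, 3 and 4 lay at 4.99, 7.25 and 6.32. Erythrocyte genes moved in part of these libraries. Slc4a1, the red cell anion exchanger, rose by 2.54 ± 0.53, and Epb42 of the red cell membrane skeleton rose by 2.90 ± 0.69. The 7 erythrocyte genes had a median of 0.87, with 1 past the threshold and 7 adjusted over the list alone (camera adjusted p = 2.72e-08, and adjusted p = 0.121 with an estimated correlation). The erythrocyte mean in carbon black replicate 1 was 8.46, inside the sham range of 8.37 to 8.91. In replicates 2, 3 and 4 it was 10.22, 10.03 and 9.69, above every day 1 sham library.

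Other changes after carbon black at day 1 were smaller. Of 11 heat shock genes 5 rose, or 7 adjusted over the list alone, among them the inducible chaperone genes Hspa1a (2.20 ± 0.42) and Hspa1b (2.29 ± 0.45), which share reads, and the co-chaperone genes Dnajb1 (0.80 ± 0.15) and Dnaja1 (0.71 ± 0.15). The list had camera adjusted p = 5.17e-13, and adjusted p = 0.0915 with an estimated correlation. The monocyte and macrophage genes F13a1 (1.62 ± 0.27), Gpnmb (0.93 ± 0.21) and Ly6c2 (0.99 ± 0.26) rose. They are 3 of 15, or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000153, and adjusted p = 0.121 with an estimated correlation). Il1b, which encodes interleukin 1 beta, rose by 2.14 ± 0.49, and Retnla by 0.95 ± 0.20. Of 22 targets of NRF2, the transcription factor of the antioxidant response, 4 rose, or 6 adjusted over the list alone. They were G6pdx (0.61 ± 0.11) and Pgd (0.33 ± 0.08) of the pentose phosphate pathway, Gsr (0.65 ± 0.15) and Hmox1 (0.46 ± 0.09), with camera adjusted p = 0.00732, and adjusted p = 0.528 with an estimated correlation. The classical target Nqo1 lay at -0.08 ± 0.30 (adjusted p = 0.96). The apelin receptor gene Aplnr of endothelial cells fell by 0.74 ± 0.19 on the log2 scale. Smooth muscle genes had a median of -0.55 with 0 of 7 past the threshold and 6 lower adjusted over the list alone (camera adjusted p = 2.69e-07, and adjusted p = 0.121 with an estimated correlation). No gene of the chemokine list of 10 passed in edgeR.

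Of the 247 genes, 234 were higher and 13 lower. The count was 114, 101 and 105 without sham replicate 1, 3 or 4. It was 75 and 89 without carbon black replicate 3 or 4, and 7 with only the compared groups in the fit. Of those 7 genes 6 were among the 247, so not all of the neutrophil genes above passed in that fit.

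**Figure D2:**
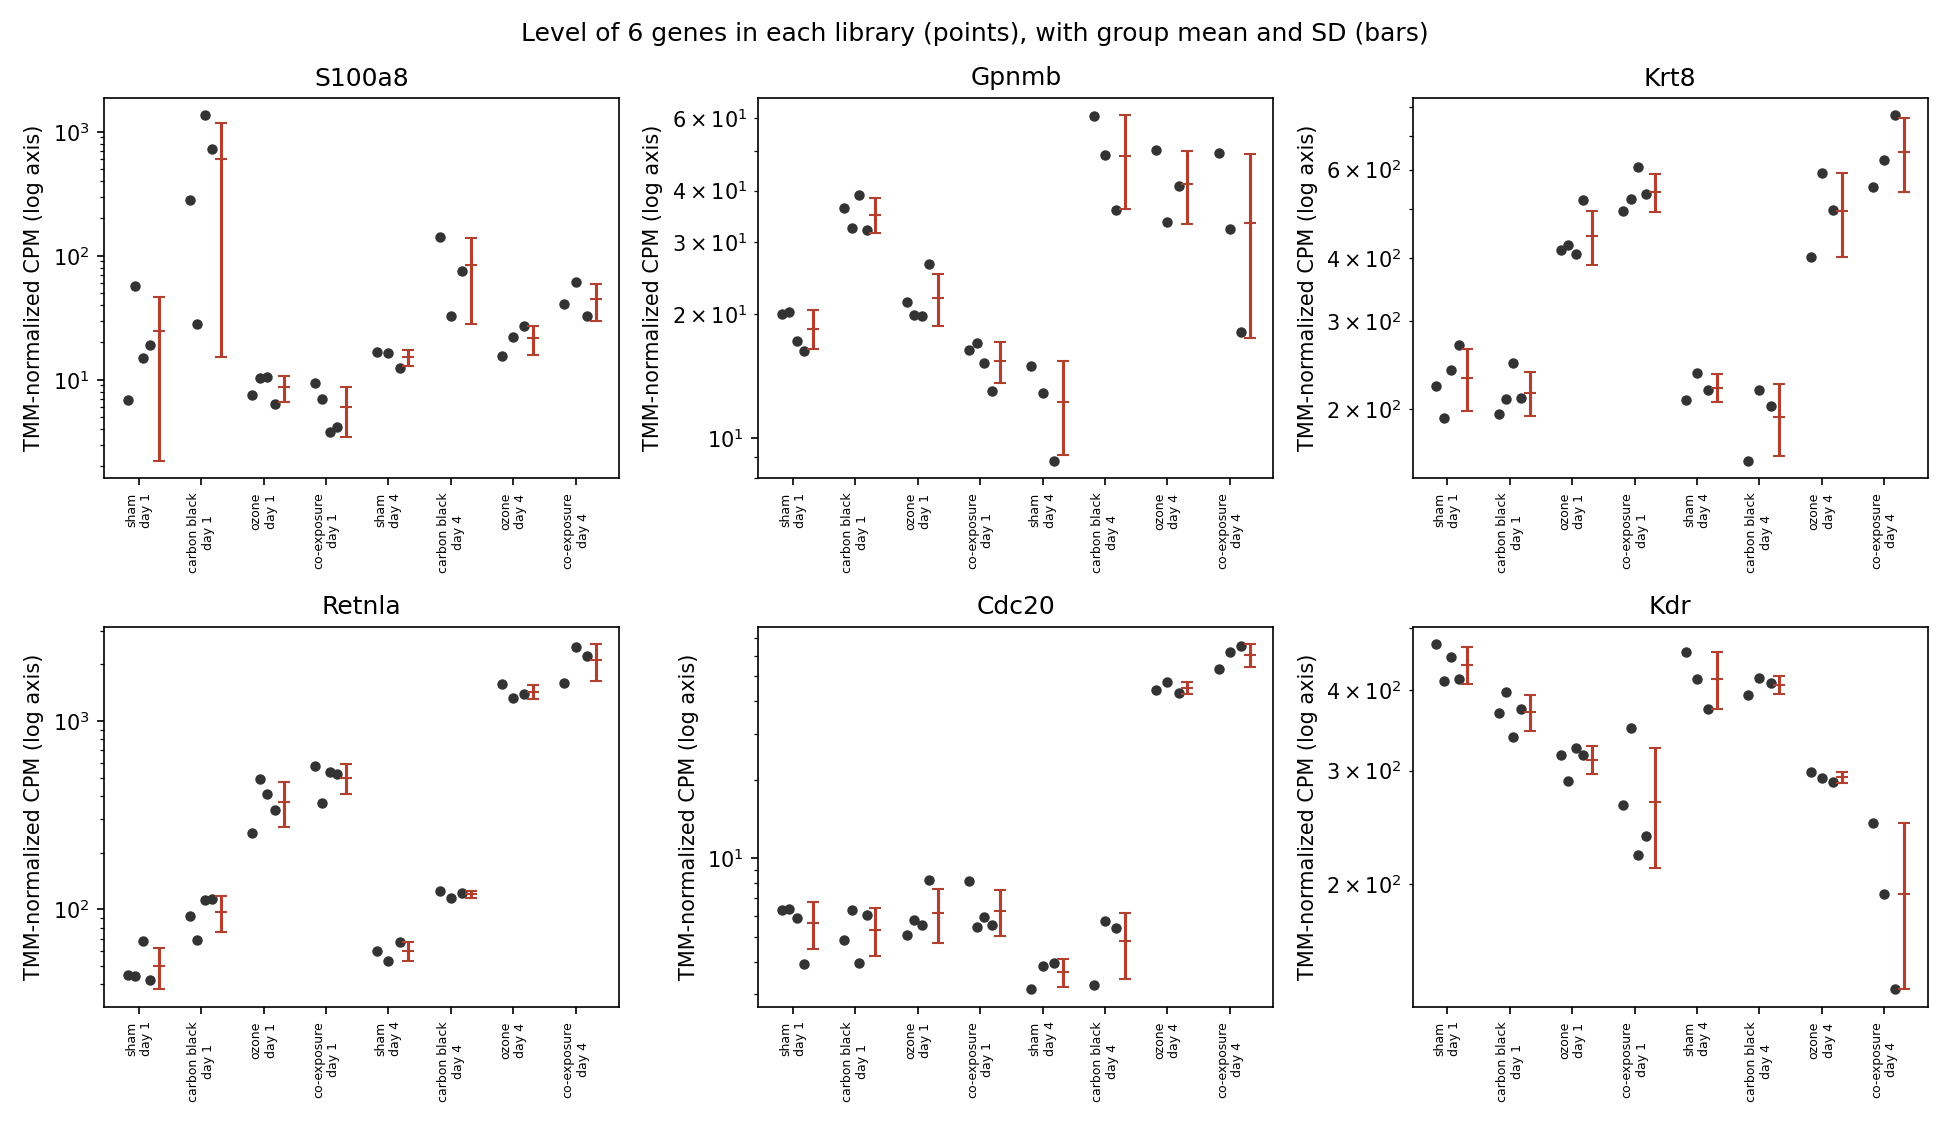
TMM-normalized CPM on a log axis of S100a8, Gpnmb, Krt8, Retnla, Cdc20 and Kdr in each of the 28 libraries (points), with group means and SD (bars, cut short where the SD would reach 0). S100a8 reached 598 CPM on average after carbon black at day 1, with replicate 2 at 28 CPM, and Cdc20 averaged 45.2 and 60.3 CPM in the day 4 ozone and co-exposure groups against 3.65 CPM in sham.

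The comparison of ozone with sham at day 1 asked what a single exposure to the oxidant gas changed. Genes of injured or transitional epithelium rose, with 14 of 16 past the threshold and, adjusted over the list alone, 15 higher and 1 lower. The list had a median of 0.92 (camera adjusted p = 1.51e-26, and adjusted p = 0.00201 with an estimated correlation). Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482), a keratin of simple epithelia, went from 231 ± 32 to 442 ± 54 CPM (SD, n = 4 each), a log2 fold change of 0.94 ± 0.13. F3, which encodes tissue factor, rose by 1.60 ± 0.15, Sfn by 1.33 ± 0.16, Krt19 by 1.09 ± 0.14 and the growth factor gene Ereg by 4.51 ± 0.55. The largest rises also held Fosl1, an AP-1 subunit (4.89 ± 0.67), Prss22 (4.40 ± 0.55), Syt8 (3.67 ± 0.58), Pbp2 (3.64 ± 0.47), the cornified envelope gene Sprr1a (3.55 ± 0.40), hemopexin (Hpx, 3.46 ± 0.31) and Psapl1 (3.01 ± 0.51).

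NRF2 targets rose after ozone, 12 of 22 higher and 2 lower, or 16 and 2 adjusted over the list alone (median 0.42, camera adjusted p = 2.52e-10, and adjusted p = 0.038 with an estimated correlation). Gclc (ENSMUSG00000032350, chromosome 9, 77754535 to 77794485), the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, went from 213 ± 19 to 453 ± 13 CPM. Nqo1 rose by 1.78 ± 0.28, Txnrd1 by 0.67 ± 0.11 and Srxn1 by 0.75 ± 0.15. Gsta1, a glutathione transferase gene whose reads can be shared with Gsta2, had 3 counts in all sham libraries and 378 after ozone, a ratio of 133 with a counting interval of 45 to 646. Metallothionein 2 (Mt2) rose by 1.96 ± 0.29, within a list of 14 glucocorticoid-responsive and metallothionein genes of which 5 rose, or 6 adjusted over the list alone, including Fkbp5 at 1.58 ± 0.27 (camera adjusted p = 0.00222, and adjusted p = 0.405 with an estimated correlation).

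Of 17 cytokine and acute-phase genes 6 rose at day 1 of ozone, also 6 adjusted over the list alone, and 11 did not pass (camera adjusted p = 2.36e-07, and adjusted p = 0.00137 with an estimated correlation). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), which encodes an iron-siderophore binding protein, went from 125 ± 10 to 514 ± 110 CPM. Saa3 rose by 1.70 ± 0.36, Lif by 1.73 ± 0.23 and Socs3 by 1.30 ± 0.15, and Orm2 was at least 14.7-fold higher, with no count in sham. Chemokines of type 2 immunity, Ccl17 (1.96 ± 0.24) and Ccl22 (1.41 ± 0.21), and Ccl7 (2.13 ± 0.51) rose, 3 of 10 or 5 adjusted over the list alone (camera adjusted p = 0.000864, and adjusted p = 0.139 with an estimated correlation). Cxcl5 lay at 1.80 ± 0.63 (adjusted p = 0.064) and Ccl2 at 1.41 ± 0.49 (adjusted p = 0.061). Retnla (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461), a secreted product of alternatively activated macrophages and epithelium, went from 49.9 ± 12 to 373 ± 100 CPM, 7.47-fold. It belongs to a list of 4 eosinophil and type 2 genes of which 2 rose, or 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000864, and adjusted p = 0.017 with an estimated correlation). The protease inhibitor gene Timp1 rose by 2.93 ± 0.28, while the list of 18 matrix genes had 4 higher and 1 lower and did not pass (camera adjusted p = 0.0873).

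Cell cycle genes rose at day 1 of ozone, with 14 of 28 higher, or 19 adjusted over the list alone (median 0.91, camera adjusted p = 1.32e-15, and adjusted p = 0.139 with an estimated correlation). The helicase subunit genes Mcm5 (1.84 ± 0.23), Mcm6 (1.05 ± 0.14) and Mcm3 (1.05 ± 0.15) led, and Mki67 rose by 1.20 ± 0.30. Genes of T and NK cells and of antigen presentation fell. Of 13 T and NK cell genes 9 were lower, or 12 adjusted over the list alone, among them Cd3g (-1.48 ± 0.28), Gzma (-1.10 ± 0.24) and Lck (-1.11 ± 0.25), with camera adjusted p = 8.84e-09, and adjusted p = 0.0695 with an estimated correlation. Of 13 B and plasma cell genes 1 was lower, or 5 adjusted over the list alone (camera adjusted p = 0.00069, and adjusted p = 0.485 with an estimated correlation). Of 13 dendritic cell and MHC class II genes 9 were lower, or 10 adjusted over the list alone, such as H2-Aa (-1.02 ± 0.16), H2-Eb1 (-1.14 ± 0.18) and Cd74 (-0.96 ± 0.16), with camera adjusted p = 1.26e-09, and adjusted p = 0.0596 with an estimated correlation. Of 21 interferon response genes 9 fell and Ifit3 rose (0.62 ± 0.14), or 14 and 1 adjusted over the list alone (camera adjusted p = 3.45e-06, and adjusted p = 0.249 with an estimated correlation). Siglech, a marker of plasmacytoid dendritic cells, lay at -1.71 ± 0.33. Of 5 aryl hydrocarbon receptor targets 3 rose and Cyp1a1 fell (-2.20 ± 0.63), the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0873). Of 15 endothelial genes 6 fell, also 6 adjusted over the list alone, led by Aplnr (-1.07 ± 0.19) and Cldn5 (-0.72 ± 0.15), with camera adjusted p = 0.000521, and adjusted p = 0.38 with an estimated correlation. Ciliated cell genes such as Tppp3 (-0.95 ± 0.17) were lower in 3 of 13, or 6 adjusted over the list alone (camera adjusted p = 8.97e-05, and adjusted p = 0.405 with an estimated correlation). Core clock genes Cry1 (1.02 ± 0.18) and Per2 (1.05 ± 0.20) rose and Nr1d1 fell (-0.86 ± 0.25), and the list of 16 did not pass (camera adjusted p = 0.277).

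Of the 1704 genes, 1014 were higher and 690 lower, and 904 passed without ozone replicate 4. Genes of other tissues varied by library at day 1. Sham replicate 2 held 607 CPM of Acta1, the actin of skeletal muscle, and 78 CPM of Ucp1, the uncoupling protein of brown fat, and ozone replicate 2 held 269 CPM of Acta1. Ucp1 passed the threshold as lower after ozone, with 2 counts against 563 in sham, and the adipose list of 6, with 1 lower or 2 adjusted over the list alone, did so as well (camera adjusted p = 0.0372, and adjusted p = 0.562 with an estimated correlation).

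The comparison of co-exposure with sham at day 1 asked what a single exposure to particle and gas together changed. Epithelial, oxidant response and acute-phase genes rose. Genes of injured or transitional epithelium were higher in 14 of 16, also 14 adjusted over the list alone, with a median of 1.23 (camera adjusted p = 4.73e-31, and adjusted p = 0.00076 with an estimated correlation). Krt8 averaged 542 ± 47 CPM against 231 ± 32 CPM in sham (SD, n = 4 each), Sfn rose by 1.85 ± 0.16, F3 by 1.72 ± 0.15, Krt7 by 1.23 ± 0.12 and Krt19 by 1.34 ± 0.14. Of 22 NRF2 targets 16 rose and 1 fell, or 16 and 2 adjusted over the list alone (camera adjusted p = 8.34e-10, and adjusted p = 0.0491 with an estimated correlation). Gclc averaged 479 ± 69 CPM against 213 ± 19 CPM, Nqo1 rose by 1.87 ± 0.28, and Gsta1 had a ratio of 203 with a counting interval of 69.2 to 989. Fosl1 (5.02 ± 0.67), Prss22 (4.70 ± 0.54), Syt8 (4.31 ± 0.56), Ereg (4.17 ± 0.55), Pbp2 (4.12 ± 0.46), Sectm1b (4.02 ± 0.54), Sprr1a (3.73 ± 0.40) and Hpx (3.47 ± 0.31) were among the largest rises beside Gsta1.

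Cytokine and acute-phase genes rose in 7 of 17 and fell in 1, or 8 and 1 adjusted over the list alone (camera adjusted p = 9.86e-08, and adjusted p = 0.00076 with an estimated correlation). Lcn2 averaged 550 ± 68 CPM against 125 ± 10 CPM in sham, Saa3 rose by 2.31 ± 0.36, Lif by 1.95 ± 0.23 and the alarmin gene Il33 by 1.26 ± 0.17. Of 10 chemokine genes 5 rose, also 5 adjusted over the list alone, with Ccl17 at 1.99 ± 0.24, Cxcl5 at 2.50 ± 0.61 and Ccl2, a chemoattractant for monocytes, at 1.75 ± 0.48 (camera adjusted p = 0.00449, and adjusted p = 0.209 with an estimated correlation). Retnla averaged 500 ± 92 CPM, 10.0-fold above sham, Timp1 rose by 3.47 ± 0.28 and Mt2 by 2.17 ± 0.29. Cell cycle genes rose in 18 of 28, also 18 adjusted over the list alone, led by Mcm6 (1.11 ± 0.14), Pcna (0.84 ± 0.11) and Mcm5 (1.80 ± 0.23), with camera adjusted p = 6.77e-15, and adjusted p = 0.165 with an estimated correlation. Of 12 ATF4 and amino acid response genes 5 rose, also 5 adjusted over the list alone, including the serine synthesis gene Psat1 (1.40 ± 0.15), with camera adjusted p = 0.00822, and adjusted p = 0.0776 with an estimated correlation. The neutrophil list had a median of -1.37 and no member past the threshold in edgeR, over all genes or over the list alone (camera adjusted p = 0.038, and adjusted p = 0.705 with an estimated correlation). S100a8 averaged 6.06 ± 2.6 CPM.

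All 13 T and NK cell genes fell, also 13 adjusted over the list alone, with a median of -1.33 (camera adjusted p = 1.79e-11, and adjusted p = 0.0491 with an estimated correlation). Gzma (-1.66 ± 0.25), Lck (-1.44 ± 0.25) and the interleukin 7 receptor gene Il7r (-1.23 ± 0.23) led them. B and plasma cell genes fell in 7 of 13, or 9 adjusted over the list alone, among them Cd22 (-1.20 ± 0.27) and Pax5 (-1.47 ± 0.33) (camera adjusted p = 9.35e-05, and adjusted p = 0.415 with an estimated correlation). MHC class II genes such as H2-Aa (-0.95 ± 0.16) and Cd74 (-0.88 ± 0.16) fell, 8 of 13 in their list, or 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 8.73e-07, and adjusted p = 0.131 with an estimated correlation). The interferon response held 12 lower genes and 1 higher of 21, or 13 and 1 adjusted over the list alone, including Gbp2 at -0.88 ± 0.14 (camera adjusted p = 3.41e-06, and adjusted p = 0.253 with an estimated correlation). Alveolar macrophage genes fell in 5 of 15, or 6 lower and 1 higher adjusted over the list alone, with Abcg1 at -0.88 ± 0.16 and Siglecf at -0.89 ± 0.22 (camera adjusted p = 0.00822, and adjusted p = 0.317 with an estimated correlation). The VEGF receptor gene Kdr (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458) averaged 268 ± 57 CPM against 438 ± 28 CPM. Endothelial genes fell in 7 of 15, or 8 adjusted over the list alone (camera adjusted p = 0.000323, and adjusted p = 0.317 with an estimated correlation). The largest falls held Sstr4 (-3.69 ± 0.65), Tmem45b (-4.17 ± 1.1) and the gluconeogenic gene Pck1 (-4.71 ± 1.5), also abundant in fat. The adipose list of 6 had a median of -2.69, with 1 lower or 6 adjusted over the list alone (camera adjusted p = 0.0364, and adjusted p = 0.589 with an estimated correlation). Ucp1 had 0 counts after co-exposure and 563 in sham, where sham replicate 2 held 78 CPM, and without that library the list had a median of -1.72 and did not pass. Across all genes the log2 fold changes had a Spearman correlation of -0.17 with exonic length.

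Of the 2854 genes, 1501 were higher and 1353 lower, and 1771 passed without co-exposure replicate 3.

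Repeated carbon black, compared with sham at day 4, raised genes of macrophages. Of 15 alveolar macrophage genes 3 rose, or 10 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 8.23e-13, and adjusted p = 0.0114 with an estimated correlation). They were Atp6v0d2, a subunit of the proton pump of lysosomes (1.43 ± 0.21), the protease gene Ctsk (1.18 ± 0.19) and Plet1 (0.87 ± 0.16). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a transmembrane glycoprotein of lipid-laden and phagocytic macrophages, went from 12.2 ± 3.2 to 48.6 ± 12 CPM (SD, n = 3 each), 3.96-fold. It ran from 8.81 to 15 CPM in day 4 sham, 16.3 to 20.3 CPM in day 1 sham and 35.9 to 60.8 CPM after repeated carbon black. The alveolar macrophage list had a lower median in day 4 sham than in day 1 sham, so the size of its rise could lean in part on day 4 sham. Among other large rises were the chemokine gene Ccl6 (1.49 ± 0.22), the C-type lectin genes Clec7a (1.28 ± 0.22) and Clec5a (1.45 ± 0.30). The scavenger receptor gene Olr1 (1.36 ± 0.24) rose too, with the zinc transporter gene Slc39a2 (1.62 ± 0.29) and Sept2 (1.32 ± 0.27). Ear6, a ribonuclease gene of a family of near-identical copies, had no count in sham and was at least 16.6-fold higher. The endothelial gene Egfl7 fell by 0.67 ± 0.14 on the log2 scale.

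Neutrophil genes after repeated carbon black had a median of 1.53, with 0 of 13 past the threshold over all genes or over the list alone in edgeR (camera adjusted p = 4.08e-05, and adjusted p = 0.622 with an estimated correlation). The neutrophil receptor gene Cxcr1, outside that list, rose by 4.2 ± 0.58. S100a8 stood at 84 ± 56 CPM against 15.2 ± 2.3 CPM. Retnla averaged 121 ± 5 CPM against 60.2 ± 6.7 CPM, and Lcn2 lay at 0.93 ± 0.25 (adjusted p = 0.12). NRF2 targets had a median of 0.09 and Gclc lay at 0.39 ± 0.13 (adjusted p = 0.16). Carbon black replicate 3 at day 4 held 123 CPM of Acta1 and 630 CPM of Myh6, the heart muscle myosin, against Myh6 at 97.4 and 165 CPM in replicates 1 and 2. Replicate 1 had the lowest total, 5.14 M estimated counts, and 7.55% mitochondrial counts, where the other libraries had 1.6 to 4.91%.

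Of the 31 genes, 24 were higher and 7 lower. The count was 653 without carbon black replicate 3 and 12 and 17 without replicate 1 or 2. It was 15, 12 and 8 without sham replicate 1, 2 or 3, 178 in DESeq2, 101 higher and 77 lower, 18 in limma-voom, 17 with length and GC trends removed and 7 with only the compared groups.

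The comparison of ozone with sham at day 4 asked what 4 exposures to the gas changed. Cell division genes rose most as a group, all 28 of 28 and also 28 adjusted over the list alone, with a median of 3.00 (camera adjusted p = 1.2e-78, and adjusted p = 0.00159 with an estimated correlation). Cdc20 (ENSMUSG00000006398, chromosome 4, 118432901 to 118437352), an activator of the anaphase-promoting complex, went from 3.65 ± 0.46 to 45.2 ± 2.3 CPM (SD, n = 3 each), 12.3-fold. The mitotic kinase gene Aurka (3.14 ± 0.22), cyclin B1 (Ccnb1, 3.88 ± 0.31), Cdk1 (3.71 ± 0.31) and Mki67 (2.98 ± 0.35) rose, as did Pimreg (4.33 ± 0.45), Hmmr (4.32 ± 0.39), Pif1 (4.27 ± 0.61), Cdc20b (4.12 ± 0.54) and Pbk (4.09 ± 0.38).

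Retnla reached 1420 ± 130 CPM against 60.2 ± 6.7 CPM in sham, 23.6-fold, and Ear6 was at least 12-fold higher. In the list of 4 eosinophil and type 2 genes 2 rose, also 2 adjusted over the list alone (camera adjusted p = 0.000496, and adjusted p = 0.0129 with an estimated correlation). Injured or transitional epithelium genes rose in 12 of 16, or 14 adjusted over the list alone (median 1.02, camera adjusted p = 8.81e-17, and adjusted p = 0.0129 with an estimated correlation). The chaperone gene clusterin (Clu) rose by 2.02 ± 0.13, the tight junction gene Cldn4 by 2.55 ± 0.27 and Sfn by 1.39 ± 0.18, and Krt8 averaged 497 ± 94 CPM against 221 ± 14 CPM. Sprr2a2, of a family with shared reads, was at least 152-fold higher, and Rps13-ps1, a pseudogene, at least 201-fold. The mucosal defence gene Dmbt1 had a ratio of 34.3 (9.12 to 289) and Psca of 20.1 (6.53 to 100). Lcn2 averaged 350 ± 37 CPM against 82.1 ± 12 CPM, and cytokine and acute-phase genes rose in 7 of 17 and fell in 1, the same numbers adjusted over the list alone (camera adjusted p = 0.000496, and adjusted p = 0.0144 with an estimated correlation).

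Matrix genes rose in 11 of 18 and fell in 1, or 13 and 1 adjusted over the list alone, with Timp1 at 2.21 ± 0.31 and the collagen genes Col1a1 (1.26 ± 0.22) and Col5a1 (0.94 ± 0.22) (camera adjusted p = 1.15e-05, and adjusted p = 0.398 with an estimated correlation). Macrophage genes Ctsk (2.24 ± 0.19), Gpnmb (1.76 ± 0.26), osteopontin (Spp1, 1.47 ± 0.27) and Trem2 (1.53 ± 0.30) rose. The alveolar macrophage list had 5 higher and 1 lower of 15, and the list of monocytes and recruited macrophages 5 higher of 15. Both had the same numbers adjusted over the list alone (camera adjusted p = 0.0399 and 0.027, and adjusted p = 0.446 and 0.401 with an estimated correlation). The matrix and alveolar macrophage lists had lower medians in day 4 sham than in day 1 sham, so the size of their rises could lean in part on day 4 sham. Mucous genes rose in 4 of 11, or 5 adjusted over the list alone, including the pendrin gene Slc26a4 (2.37 ± 0.26), Agr2 (2.35 ± 0.59) and the mucin gene Muc5ac (1.00 ± 0.33) (camera adjusted p = 0.00916, and adjusted p = 0.46 with an estimated correlation). Club cell genes, of the secretory cells of the small airways, fell in 6 of 12, also 6 adjusted over the list alone, with Cyp2f2 at -1.02 ± 0.18 and Scgb1a1 at -1.05 ± 0.25 (camera adjusted p = 0.00478, and adjusted p = 0.446 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 16, or 10 adjusted over the list alone, such as Dhcr7 (0.70 ± 0.14) and Cyp51 (0.50 ± 0.12) (camera adjusted p = 0.000496, and adjusted p = 0.398 with an estimated correlation). Alveolar type 1 genes Pdpn (0.59 ± 0.13) and Aqp5 (0.50 ± 0.12) rose, and their list of 11 did not pass (camera adjusted p = 0.228).

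Endothelial genes fell in 12 of 15, or 13 adjusted over the list alone (median -0.72, camera adjusted p = 2.99e-08, and adjusted p = 0.142 with an estimated correlation), with Egfl7 at -0.87 ± 0.14 and the endothelin receptor gene Ednrb at -0.95 ± 0.18. Kdr averaged 293 ± 5.6 CPM against 416 ± 42 CPM. Glucocorticoid-responsive genes such as Tsc22d3 (-1.60 ± 0.19) and Klf9 (-1.24 ± 0.18) fell, 6 of 14 with 2 higher, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.00371, and adjusted p = 0.401 with an estimated correlation). Immediate early genes, including Dusp1 (-1.75 ± 0.28) and Jun (-0.68 ± 0.15), fell in 5 of 15, or 6 adjusted over the list alone (camera adjusted p = 0.00226, and adjusted p = 0.398 with an estimated correlation). Among T and NK cell genes Cd3d lay at -1.34 ± 0.29, and among B cell genes Cd79a lay at -1.21 ± 0.39. The T and NK list had 7 of 13 lower, or 8 adjusted over the list alone, and the B and plasma cell list 4 of 13, or 8 adjusted over the list alone (camera adjusted p = 0.000496 and 0.00169, and adjusted p = 0.398 and 0.463 with an estimated correlation). The J chain gene of plasma cells, Jchain (-5.45 ± 1.9), and the immunoglobulin segment Iglv1 (-3.97 ± 1.3), whose reads can be shared, fell as well. Erythrocyte genes fell in 6 of 7, or 7 adjusted over the list alone, with the hemoglobin gene Hba-a1 at -1.63 ± 0.35 (camera adjusted p = 0.000179, and adjusted p = 0.398 with an estimated correlation). Their mean log2 CPM was 8.39, 8.4 and 7.74 in ozone replicates 1, 2 and 3, and sham replicates 1 and 2 (10.18 and 9.73) stood apart from sham replicate 3 (8.6) and from day 1 sham (8.37 to 8.91), so the size of the fall leans on those 2 libraries. Heart muscle genes were lower in 7 of 8, also 7 adjusted over the list alone, with Myh6 at 58.6 to 81.6 CPM in the ozone libraries and 178 to 344 CPM in sham (camera adjusted p = 0.000496, and adjusted p = 0.401 with an estimated correlation). NRF2 targets had 5 higher and 2 lower of 22, the same adjusted over the list alone, with Gclc at 1.01 ± 0.13 and the glutathione transferase gene Gstm1 at -1.13 ± 0.12, and the list did not pass (camera adjusted p = 0.29). The neutrophil list did not pass (camera adjusted p = 0.228), and the granule gene Ltf rose by 2.64 ± 0.75.

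Of the 3089 genes, 1739 were higher and 1350 lower. Among genes higher at day 1 of ozone, 523 were also higher at day 4, where independent lists would share 118.4, and 278 were lower at both days, where 62.6 would be shared.

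The comparison of co-exposure with sham at day 4 asked what 4 exposures to particle and gas together changed. All 28 cell cycle genes rose, also 28 adjusted over the list alone, with a median of 3.51 (camera adjusted p = 1.39e-64, and adjusted p = 0.00452 with an estimated correlation). Cdc20 averaged 60.3 ± 6.2 CPM against 3.65 ± 0.46 CPM in sham (SD, n = 3 each), 16.5-fold, Cdk1 rose by 4.35 ± 0.31, Ccnb1 by 4.18 ± 0.31, Aurka by 3.56 ± 0.22 and Mki67 by 3.22 ± 0.35. Retnla averaged 2090 ± 460 CPM, 34.7-fold above sham. Its list of 4 had 2 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.00289, and adjusted p = 0.0233 with an estimated correlation), with Ear6 at least 12.7-fold higher and the interleukin 33 receptor gene Il1rl1 at -1.08 ± 0.27.

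Epithelial injury genes rose in 14 of 16, also 14 adjusted over the list alone (median 1.16, camera adjusted p = 2.06e-16, and adjusted p = 0.0213 with an estimated correlation). Clu rose by 2.28 ± 0.13, Cldn4 by 2.77 ± 0.27 and Sfn by 1.77 ± 0.18, and Krt8 averaged 650 ± 110 CPM against 221 ± 14 CPM. Genes with 3 or fewer counts in sham that rose included Sprr2a2 (at least 184-fold), Pbp2 (at least 18-fold), the calretinin gene Calb2 (at least 16.5-fold), Prss22 (76.4, interval 13.3 to 3060), Ptchd3 (64, interval 11 to 2570), Tsga10ip (62.9, interval 10.8 to 2530) and the transporter gene Slc47a2 (32.2, interval 10.7 to 159). Cytokine and acute-phase genes rose in 10 of 17, or 11 adjusted over the list alone (camera adjusted p = 0.00105, and adjusted p = 0.0233 with an estimated correlation). Lcn2 averaged 357 ± 21 CPM against 82.1 ± 12 CPM, Orm2 rose by 3.82 ± 0.63 and Il33 by 1.46 ± 0.20. Among chemokine genes Ccl2 (2.14 ± 0.58), Cxcl10 (1.46 ± 0.40) and Cxcl5 (2.47 ± 0.79) rose with Ccl17, 4 of 10 or 5 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0967). Matrix genes had 9 higher and 2 lower of 18, or 11 and 2 adjusted over the list alone, with Timp1 at 2.85 ± 0.31 (camera adjusted p = 0.00459, and adjusted p = 0.574 with an estimated correlation). The size of the matrix rise could again lean in part on the lower median of this list in day 4 sham. Macrophage genes Spp1 (1.97 ± 0.27), Trem2 (1.74 ± 0.30) and arginase 1 (Arg1, 1.83 ± 0.35) rose, in a list with 6 higher and 1 lower of 15, the same adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.371 with an estimated correlation). Agr2 of mucous cells rose by 3.6 ± 0.59, with 3 of 11 genes of its list higher, also 3 adjusted over the list alone (camera adjusted p = 0.0214, and adjusted p = 0.574 with an estimated correlation). Metallothionein genes Mt1 (1.59 ± 0.24) and Mt2 (1.94 ± 0.33) rose while Per1 (-1.75 ± 0.19) and Tsc22d3 (-1.34 ± 0.19) fell. Their list of 14 had 2 higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.0458, and adjusted p = 0.58 with an estimated correlation). With the replicate number as a block its median was -0.51 and the list did not pass.

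Endothelial genes fell in 13 of 15, or 14 adjusted over the list alone, with a median of -1.11 (camera adjusted p = 3.98e-12, and adjusted p = 0.0378 with an estimated correlation). Kdr averaged 193 ± 56 CPM against 416 ± 42 CPM in sham, and the angiopoietin receptor gene Tek (-1.28 ± 0.18) and Ednrb (-1.27 ± 0.18) fell. Lymphocyte genes fell, with 10 of 13 T and NK cell genes lower, or 13 adjusted over the list alone, and 9 of 13 B and plasma cell genes lower, also 9 adjusted over the list alone (camera adjusted p = 0.000206 and 0.00142, and adjusted p = 0.322 and 0.574 with an estimated correlation). Examples are the T and NK cell genes Il7r (-1.42 ± 0.27) and Gzma (-1.47 ± 0.28). All 7 erythrocyte genes fell, also 7 adjusted over the list alone, such as Hbb-bs at -2.02 ± 0.35 (camera adjusted p = 4.09e-05, and adjusted p = 0.322 with an estimated correlation). The size of this fall leans on the same 2 sham libraries, as the erythrocyte mean was 7.59, 7.98 and 7.29 after co-exposure and 8.6 in sham replicate 3. Dendritic cell and MHC class II genes fell in 8 of 13 with Fscn1 higher (1.00 ± 0.22), or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00915, and adjusted p = 0.574 with an estimated correlation). The largest falls held Igfbp3 (-3.24 ± 0.28), Fam124b (-3.37 ± 0.55) and Apol11b (-2.77 ± 0.64). Mitochondrial respiratory chain genes rose in 11 of 22, or 16 adjusted over the list alone, with Cox5a at 0.84 ± 0.18 and Cox7a2 at 0.54 ± 0.13 (camera adjusted p = 0.00125, and adjusted p = 0.574 with an estimated correlation). These are short genes, and the log2 fold changes of all genes had a Spearman correlation of -0.20 with exonic length. The NRF2 list did not pass (7 higher and 2 lower of 22, the same adjusted over the list alone, camera adjusted p = 0.0927).

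Of the 5073 genes, 2639 were higher and 2434 lower, and 3175 passed with only the compared groups in the fit. Between days 906 genes were higher after co-exposure at both, where independent lists would share 266.1, and 696 were lower at both, where 221.2 would be shared.

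**Figure D3:**
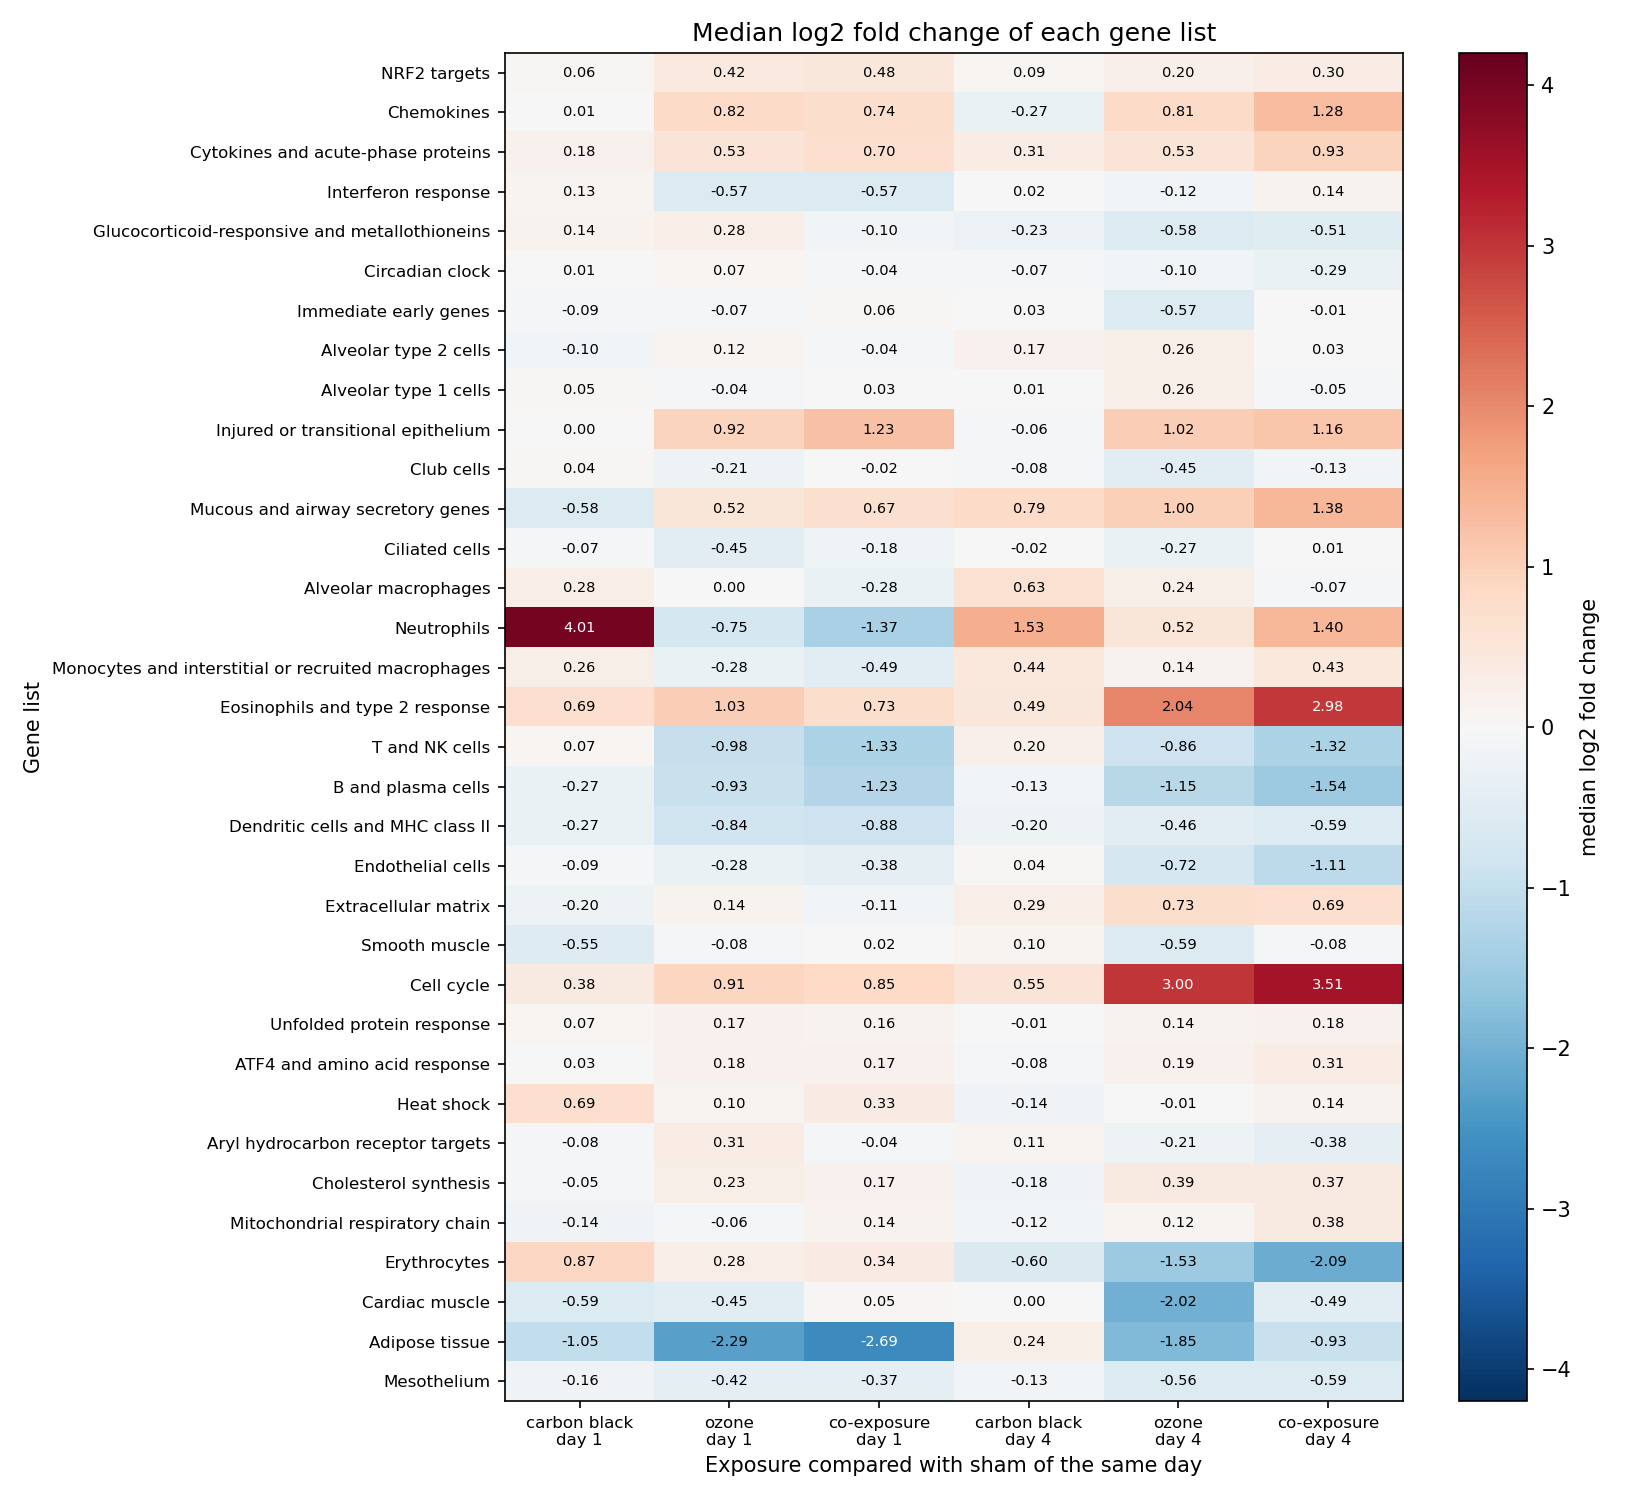
Median log2 fold change of each of the 34 gene lists (lines) in the 6 comparisons of an exposure with sham of its day (columns), with the value printed in each field. Neutrophil genes had a median of 4.01 after carbon black at day 1, and cell cycle genes of 3.00 and 3.51 after ozone and co-exposure at day 4.

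Whether particle and gas together differed from ozone alone was tested directly. At day 1 no gene passed in edgeR, with 2337 genes at an unadjusted p under 0.05, 39 genes in DESeq2 and none in limma-voom. Krt8 differed by 0.29 ± 0.13 (adjusted p = 0.28), Retnla averaged 500 ± 92 CPM after co-exposure and 373 ± 100 CPM after ozone, and Gclc differed by 0.08 ± 0.11 (adjusted p = 0.74). Alveolar macrophage genes were lower as a list, with a median of -0.48, 0 of 15 past the threshold and 4 adjusted over the list alone (camera adjusted p = 7.72e-06, and adjusted p = 0.28 with an estimated correlation). Injured or transitional epithelium genes were higher, with a median of 0.23 and 0 of 16 past the threshold, or 2 adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.928 with an estimated correlation). Respiratory chain genes had a median of 0.20 with 0 of 22 past the threshold, or 4 adjusted over the list alone (camera adjusted p = 0.00027, and adjusted p = 0.928 with an estimated correlation). Log2 differences correlated with exonic length at a Spearman rho of -0.40 across genes.

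At day 4 co-exposure and ozone alone again gave no gene past the threshold in edgeR, with 2991 genes at an unadjusted p under 0.05, 490 in DESeq2 and 96 in limma-voom. Cxcl5 differed by 1.87 ± 0.74 (adjusted p = 0.17), Mki67 by 0.24 ± 0.31 (adjusted p = 0.69) and Krt8 by 0.39 ± 0.15 (adjusted p = 0.15). Endothelial genes were lower as a list, with a median of -0.32, 0 of 15 past the threshold and 4 lower adjusted over the list alone (camera adjusted p = 3.11e-05, and adjusted p = 0.58 with an estimated correlation). Kdr averaged 193 ± 56 CPM after co-exposure and 293 ± 5.6 CPM after ozone. It is a long gene, with 9030 bases of exons. In co-exposure replicates 1, 2 and 3 it lay at 249, 193 and 137 CPM. The deviations of these libraries correlated with exonic length at -0.05, -0.34 and -0.34, so the values do not separate the Kdr difference from a length trend. Cell cycle genes had a median of 0.33, with 0 of 28 past the threshold and 1 adjusted over the list alone (camera adjusted p = 0.000196, and adjusted p = 0.58 with an estimated correlation). Respiratory chain genes had a median of 0.27, with 0 of 22 and 10 adjusted over the list alone (camera adjusted p = 1.46e-05, and adjusted p = 0.58 with an estimated correlation). The rho with exonic length was -0.34, and co-exposure replicate 3 held 215 CPM of Acta1 and 257 CPM of Myh6, where replicates 1 and 2 held under 0.5 CPM of Acta1. Without co-exposure replicate 1 the count was 2769, and with the stricter low-count filter it was 26. With the replicate number as a block it was 154, 78 higher and 76 lower. Deviations of same-numbered ozone and co-exposure libraries correlated at only 0.03, 0.06 and 0.01 at day 4.

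**Figure D4:**
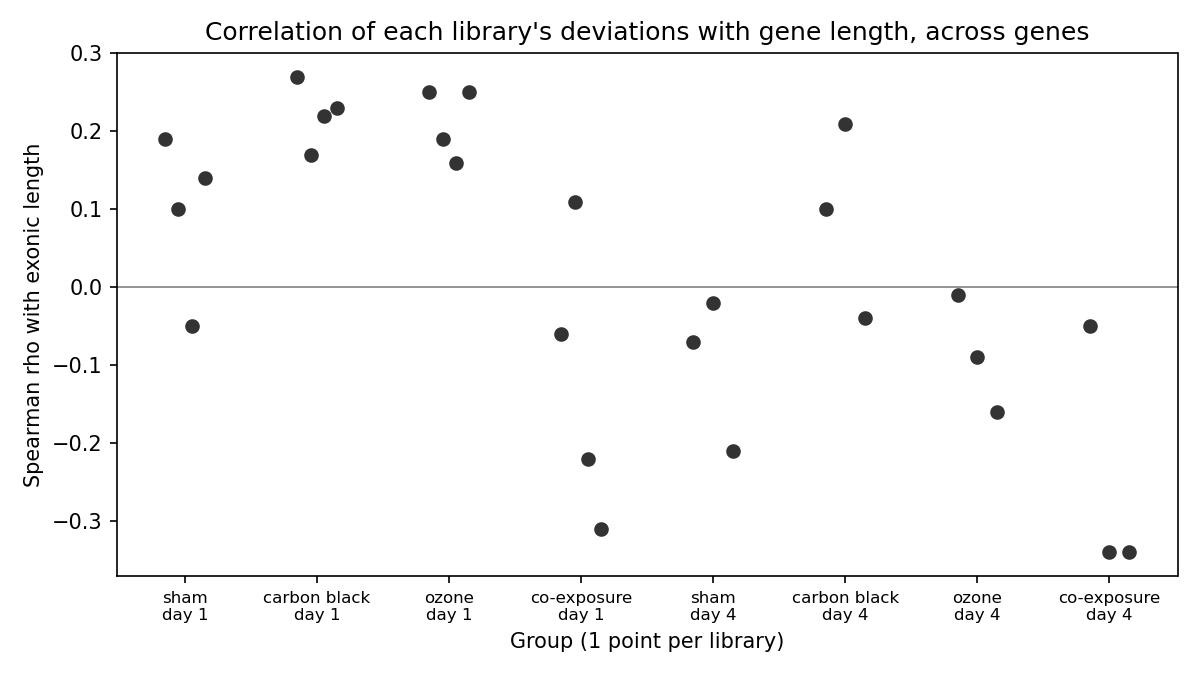
Spearman correlation across genes between each library's deviation in log2 CPM and exonic gene length (vertical axis, no unit), with 1 point per library and the 8 groups along the horizontal axis. The day 1 ozone libraries lie at 0.16 to 0.25 and the day 1 co-exposure libraries at -0.31 to 0.11.

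Co-exposure against carbon black alone gave 3849 genes at day 1, 1956 higher and 1893 lower. Neutrophil genes were lower in 12 of 13 and Ltf was higher, the same numbers adjusted over the list alone, with a median of -4.97 (camera adjusted p = 3.01e-10, and adjusted p = 0.119 with an estimated correlation). The carbon black libraries are those compared with sham at day 1, where replicate 2 did not share the neutrophil rise. This difference is thus not independent of that rise. S100a8 differed by -6.61 ± 0.92, S100a9 by -6.73 ± 0.94 and Slfn4 by -6.15 ± 0.72, and Ngp had 2 counts after co-exposure and 530 after carbon black, a ratio of 246 with a counting interval of 67.7 to 2030. Monocyte and recruited macrophage genes were lower in 8 of 15 and higher in 2, the same adjusted over the list alone, with F13a1 at -2.41 ± 0.28 and Ccr2 at -1.92 ± 0.32 (camera adjusted p = 6.02e-05, and adjusted p = 0.108 with an estimated correlation). Injured or transitional epithelium genes were higher in 13 of 16, also 13 adjusted over the list alone, with Krt8 at 1.33 ± 0.13 and F3 at 1.77 ± 0.15 (camera adjusted p = 1.81e-26, and adjusted p = 0.00418 with an estimated correlation). Gsta1 (7.08 ± 0.74), Pbp2 (4.87 ± 0.50) and Timp1 (3.43 ± 0.28) were higher, and Hspa1a (-1.86 ± 0.41) was lower. The count was 2534 without co-exposure replicate 3, and rho with exonic length was -0.26.

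At day 4, 5687 genes differed between co-exposure and carbon black, 2872 higher and 2815 lower. All 28 cell cycle genes were higher, also 28 adjusted over the list alone, with Cdc20 at 3.61 ± 0.21 (camera adjusted p = 1.25e-48, and adjusted p = 0.0166 with an estimated correlation). Epithelial injury genes were higher in 14 of 16, also 14 adjusted over the list alone, with Clu at 2.11 ± 0.13 and Krt18 at 1.72 ± 0.18 (camera adjusted p = 6.05e-18, and adjusted p = 0.0166 with an estimated correlation). Saa3 (3.19 ± 0.41), Cxcl10 (2.62 ± 0.45) and the hyaluronan synthase gene Has2 (4.73 ± 0.82) were higher, and Cyp1a1 (-3.61 ± 0.72), Igfbp3 (-3.15 ± 0.28) and the alveolar macrophage gene Fabp1 (-2.06 ± 0.28) were lower. Endothelial genes were lower in 12 of 15, or 13 adjusted over the list alone, with Plvap at -1.22 ± 0.17 (camera adjusted p = 7.83e-10, and adjusted p = 0.118 with an estimated correlation). With only the compared groups in the fit 2373 genes passed.

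The interaction asked whether the co-exposure change departed from the sum of both single changes on the log2 scale, and a negative value means that co-exposure lay lower than that sum. At day 1, 218 genes passed, 33 higher and 185 lower. Retnlg (-5.40 ± 1.2), S100a8 (-5.14 ± 1.2), S100a9 (-5.05 ± 1.2) and Mgam (-4.40 ± 0.96) were among the lowest, and 6 of 13 neutrophil genes were lower, or 11 adjusted over the list alone (camera adjusted p = 1.39e-12, and adjusted p = 0.194 with an estimated correlation). The same day 1 carbon black libraries enter here, so these values are not independent of the neutrophil rise against sham, which replicate 2 did not share. Alveolar macrophage genes were lower in 5 of 15, or 8 adjusted over the list alone, including the mannose receptor gene Mrc1 (-1.32 ± 0.24) and Atp6v0d2 (-1.25 ± 0.25) (camera adjusted p = 4.25e-07, and adjusted p = 0.17 with an estimated correlation). F13a1 lay at -2.13 ± 0.39 and Tiparp, a target of the aryl hydrocarbon receptor, at -0.67 ± 0.12. The count was 129, 343, 82 and 76 without sham replicate 1, 2, 3 or 4. It was 387, 90 and 89 without carbon black replicate 2, 3 or 4, 137, 86, 132 and 141 without ozone replicate 1, 2, 3 or 4, and 471, 71 and 56 without co-exposure replicate 2, 3 or 4. In DESeq2 it was 521, 150 higher and 371 lower, and with only the day 1 groups it was 898, 470 higher and 428 lower, so the lean to lower values was not kept there. Spearman rho with exonic length was -0.38.

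At day 4 the interaction called 204 genes, 114 higher and 90 lower. Macrophage genes were lower than the sum, with Gpnmb at -2.30 ± 0.35, Atp6v0d2 at -1.84 ± 0.28 and Ctsk at -1.34 ± 0.26. Ear6, of the eosinophil and type 2 list, lay at -6.93 ± 1.4, a fitted value that depends on the prior count because sham had no count. Alveolar macrophage genes were lower in 5 of 15, or 9 adjusted over the list alone (camera adjusted p = 9.25e-08, and adjusted p = 0.107 with an estimated correlation). Day 4 sham, where this list had a lower median than in day 1 sham, enters the interaction. Klf2, an endothelial and lymphocyte transcription factor gene, lay at 1.43 ± 0.29. The count was 114 and 0 without sham replicate 2 or 3, 11, 6 and 1293 without carbon black replicate 1, 2 or 3. It was 2, 10 and 31 without ozone replicate 1, 2 or 3, and 2979, 4 and 3 without co-exposure replicate 1, 2 or 3. It was 1037 in DESeq2, 468 higher and 569 lower, 64 without the low-count filter, 30 with length and GC trends removed, 12 higher and 18 lower, and 0 in edgeR with only the day 4 groups, and rho with exonic length was -0.36. With the replicate number as a block the count was 879, 357 higher and 522 lower, so the lean to higher values was not kept there.

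The change after each exposure was also compared between days. For ozone 631 genes differed, 351 with a higher and 280 with a lower value at day 4. Cell cycle genes were higher in 20 of 28, or 23 adjusted over the list alone, with Cdc20 at 3.49 ± 0.28 (camera adjusted p = 4.01e-52, and adjusted p = 0.0123 with an estimated correlation). Clu (1.36 ± 0.17), Col1a1 (1.55 ± 0.29) and Retnla (1.66 ± 0.29) were higher at day 4. Both sham groups enter this difference, and matrix genes as a list had a lower median in day 4 sham than in day 1 sham. NRF2 targets were lower in 4 of 22, or 5 adjusted over the list alone, with Nqo1 at -1.71 ± 0.44 and Gsta1 at -6.73 ± 1.4, a fitted value from sham groups near 0 counts (camera adjusted p = 0.0003, and adjusted p = 0.245 with an estimated correlation). F3 (-1.23 ± 0.23) and Tsc22d3 (-1.37 ± 0.24) were lower, with 7 of 14 glucocorticoid-responsive and metallothionein genes, or 9 adjusted over the list alone (camera adjusted p = 1.59e-09, and adjusted p = 0.151 with an estimated correlation). The count was 365 without day 1 ozone replicate 1, 397, 385 and 367 without day 4 ozone replicate 1, 2 or 3, 368 without day 4 sham replicate 2, and 1125 with only the compared groups.

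For co-exposure 1522 genes differed between days, 810 with a higher and 712 with a lower value at day 4. Cell cycle genes were higher in 22 of 28, or 24 adjusted over the list alone, with Cdc20 at 3.88 ± 0.28 (camera adjusted p = 9.52e-47, and adjusted p = 0.0232 with an estimated correlation). Monocyte and macrophage genes were higher in 6 of 15, or 9 adjusted over the list alone, with Gpnmb at 1.71 ± 0.34 and the Fc receptor gene Fcgr1 at 1.81 ± 0.39 (camera adjusted p = 5.08e-07, and adjusted p = 0.0723 with an estimated correlation). Il1b (3.71 ± 0.85), Clu (1.59 ± 0.17) and Col1a1 (1.70 ± 0.29) were higher, and Nqo1 (-1.34 ± 0.43), Gsta1 (-5.75 ± 1.4, from sham groups near 0 counts), Per1 (-1.53 ± 0.25) and Egfl7 (-0.84 ± 0.19) were lower. The lower median of matrix genes in day 4 sham bears on this difference as well. Endothelial genes were lower in 7 of 15, or 9 adjusted over the list alone (camera adjusted p = 9.77e-08, and adjusted p = 0.165 with an estimated correlation).

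For carbon black 14 genes differed between days, 1 with a higher and 13 with a lower value at day 4. The platelet genes Ppbp (-2.35 ± 0.39), Gp5 (-2.43 ± 0.44) and Treml1 (-2.66 ± 0.49) and the heat shock gene Dnajb1 (-1.34 ± 0.23) were lower, and Cip2a (1.47 ± 0.29) was higher. Heat shock genes were lower in 1 of 11, or 6 adjusted over the list alone (camera adjusted p = 7.48e-12, and adjusted p = 0.179 with an estimated correlation). The count was 2 without day 4 sham replicate 1, 42 without day 1 carbon black replicate 1, 9 without day 4 carbon black replicate 1, 36 in DESeq2 and 2 with only the compared groups. Between the sham groups, erythrocyte genes were higher at day 4 with a median of 1.02 and 0 of 7 past the threshold in edgeR, or 7 adjusted over the list alone (camera adjusted p = 1.48e-07, and adjusted p = 0.449 with an estimated correlation).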

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

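The comparison of neutrophil with erythrocyte genes, the checks for a swapped library and the comparison of length trends by library were chosen only after their results were seen.

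The rise of neutrophil genes after 1 carbon black exposure was weighed against blood left in the lungs, trends with gene length and GC content, and a swapped library. Neutrophil genes rose on average by 2.89 and erythrocyte genes by 0.95, a difference of 1.94 with a standard error of 1.06. The difference is under 2 standard errors, so this comparison does not exclude blood as the source of the rise. By library the means did not move together. Carbon black replicate 2 had an erythrocyte mean of 10.22 with a neutrophil mean of 3.02. Day 4 sham replicates 1 and 2 had 10.18 and 9.73 with 2.4 and 2.35. Carbon black replicates 3 and 4 had 10.03 and 9.69 with 7.25 and 6.32, and replicate 1 had 8.46 with 4.99. These values, read after they were seen, argue only against blood like that in sham as the main source. Blood richer in neutrophils than that in sham stays open. With length and GC trends removed 12 of 13 genes still passed, and the median was 4.04 against 4.01, which argues against those trends. In their mean over neutrophil genes carbon black replicates 1, 3 and 4 lay at least 1.7 above the highest sham library, which argues against a library like these among sham. This check set carbon black replicate 2 aside and used the genes of the pattern itself. A wrong label of that library, or its exchange with sham replicate 2, stays open. Over 313 other genes, chosen without carbon black replicate 2, its difference from sham replicate 2, the highest sham library, was -0.01. Both lay at 4, the other sham libraries at 3.5 to 3.56 and the other carbon black libraries at 4.53 to 5.24, which cannot tell. Recruitment of neutrophils by the particle is a hypothesis that was not tested.

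Short genes lay higher and long genes lower in co-exposure than in ozone libraries, with a Spearman rho of -0.40 at day 1 and -0.34 at day 4. With length and GC trends removed the respiratory chain list kept 53.1% of its median at day 1 and 39.7% at day 4, with camera adjusted p = 0.038 and 0.00454 in limma, so a technical trend could explain a part and the test cannot tell. None of the 4 day 1 co-exposure libraries and 1 of the 3 at day 4 overlapped the ozone libraries in its length correlation, so the trend is not in every co-exposure library. Exposure and any difference in library preparation cannot be separated by the labels used here.

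Genes lower in the day 1 interaction were weighed against the same trends. With the trends removed 126 of 185, or 68.1%, were still lower, and the median of the 185 genes was -1.20 against -1.25, which argues against length and GC as the main cause. With only the day 1 groups 470 genes were higher and 428 lower, so the lean to lower values depends on the fit. No biological explanation was tested.

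A difference between exposures or days marked the other results. The interaction had 218 genes at day 1 and 204 at day 4, and the change between days had 14 genes for carbon black, 631 for ozone and 1522 for co-exposure. In the day 1 interaction the log2 values were -5.40 for Retnlg, -5.14 for S100a8, -5.05 for S100a9, -4.40 for Mgam, -1.32 for Mrc1, -1.25 for Atp6v0d2, -2.13 for F13a1 and -0.67 for Tiparp. In the day 4 interaction they were -2.30 for Gpnmb, -1.84 for Atp6v0d2, -1.34 for Ctsk, -6.93 for Ear6 and 1.43 for Klf2. Between days after carbon black they were -2.35 for Ppbp, -2.43 for Gp5, -2.66 for Treml1, -1.34 for Dnajb1 and 1.47 for Cip2a. After ozone they were 3.49 for Cdc20, -1.71 for Nqo1, -6.73 for Gsta1, -1.37 for Tsc22d3, 1.36 for Clu, 1.55 for Col1a1, 1.66 for Retnla and -1.23 for F3. After co-exposure they were 3.88 for Cdc20, -1.34 for Nqo1, -5.75 for Gsta1, -1.53 for Per1, 1.59 for Clu, 1.70 for Col1a1, 1.71 for Gpnmb, 1.81 for Fcgr1, 3.71 for Il1b and -0.84 for Egfl7.

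Single day 1 libraries lay far from the others of their group by Dixon's test, in 9 of 56 groups of values, where chance marks about 1 in 20. Carbon black replicate 1 had 9.72 M estimated counts, sham replicate 2 had 2.82% mitochondrial counts, sham replicate 3 had 68.2 CPM of Retnla and ozone replicate 4 had 523 CPM of Krt8. The chance rate does not apply to Acta1, Ucp1 and Myh6, which were chosen after their values were seen. They are part of the 56 groups, so 9 of 56 cannot be set against that rate. Acta1 stood at 607 CPM in sham replicate 2, 269 CPM in ozone replicate 2 and 2.85 CPM in co-exposure replicate 4. Ucp1 stood at 78 CPM in sham replicate 2 and 3.80 CPM in carbon black replicate 2.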

How the results depend on the processing

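The fit without the robust option, the list leave-outs and the removal of length and GC trends were chosen after seeing the data. Of 910 named gene values past the threshold none changed direction. Apart from the fixed genes these were chosen for large changes or small p in the same counts, so refits could hardly reverse them. Values for which an alternative gave no adjusted p were not counted, which is why some totals below are smaller than 910. Still past it were 906 with median-of-ratios scaling, 904 without the robust option, 819 without the low-count filter, 843 with length and GC trends removed, 833 in limma-voom, 893 of 895 in DESeq2, 892 of 895 with the stricter filter, 754 of 886 with only the compared groups, and 6372 of 7542 with 1 library left out. The pooled share with only the compared groups does not hold for every comparison. Over all called genes, that fit kept 6 of 247 for carbon black at day 1 and 3 of 31 at day 4. It kept 1 of 14 for the carbon black day difference and 0 of 204 for the day 4 interaction. Of 215 list calls 27 remained with an estimated correlation, 124 with fry, 195 with length and GC trends removed, 214 with median-of-ratios scaling and 212 with the stricter filter. With 1 library left out 1791 of 1984 remained, 190 were lost and 3 reversed. With 3 or 4 libraries per group and 5.14 M to 9.72 M counts per library, a gene with no count in a library could lie anywhere up to 0.309 to 0.584 CPM.

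Counts of genes that moved by over 1.5 times follow, and the cause was not tested except where fewer libraries or genes entered. DESeq2 gave 178 (101 higher) for carbon black at day 4, 39 and 490 for co-exposure against ozone at day 1 and day 4, 521 (150 higher) and 1037 (468 higher) for the interaction at day 1 and day 4, and 36 for the carbon black day difference. Limma-voom gave 18 for carbon black at day 4 and 96 for co-exposure against ozone at day 4. Without the low-count filter the day 4 interaction had 64, and with the stricter filter co-exposure against ozone at day 4 had 26. With length and GC trends removed carbon black at day 4 had 17 and the day 4 interaction 30. With co-exposure replicate 1 also left out, co-exposure against ozone at day 4 had 1560. With only the compared groups the counts were 7 for carbon black at each day, 3175 for co-exposure at day 4, 2373 for co-exposure against carbon black at day 4, 898 (470 higher and 428 lower) and 0 for the interaction at day 1 and day 4, 2 for the carbon black and 1125 for the ozone day difference.

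With the replicate number as a block the count was 154 for co-exposure against ozone at day 4, 78 higher and 76 lower. It was 879 for the day 4 interaction, 357 higher and 522 lower. No other count moved by over 1.5 times, and 873 of 910 named values and 211 of 215 list calls remained. For sham and co-exposure at day 4, where all 3 pairs lay above 0.1, the count was 5125 against 5073. The correlation of deviations between libraries with the same number had a median of 0.05 over 24 pairs at day 1 (-0.25 to 0.37) and 0.04 over 18 pairs at day 4 (-0.1 to 0.48). A library correlated best with its own number in 6 and 8 of these.

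Leaving out 1 library gave ranges of 75 to 357 for carbon black, 904 to 1519 for ozone and 1771 to 2967 for co-exposure at day 1, and of 8 to 653 for carbon black at day 4. Co-exposure against carbon black at day 1 ranged from 2534 to 4127 and co-exposure against ozone at day 4 from 0 to 2769. The interaction ranged from 56 to 471 at day 1 and from 0 to 2979 at day 4, and the day difference from 2 to 42 for carbon black and from 365 to 624 for ozone. The adipose list median after carbon black at day 1 ranged from -3.00 to 0.32, positive without sham replicate 2. The glucocorticoid list median ranged from -0.01 to 0.21 for carbon black at day 1, negative without carbon black replicate 3, and from -0.21 to 0.06 between sham groups, positive without day 4 sham replicate 1.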

Other observations

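No test in this part was chosen only after its result was seen, but the number of splits for interactions and day differences was raised after a first run. Between the sham groups of both days, where no gene passed in edgeR, several lists moved without a member past the threshold. Alveolar macrophage genes had a median of -0.45 with 0 of 15 (camera adjusted p = 2.65e-05, and adjusted p = 0.449 with an estimated correlation). Matrix genes had a median of -0.42 with 0 of 18, or 5 lower adjusted over the list alone (camera adjusted p = 1.48e-07, and adjusted p = 0.626 with an estimated correlation). Alveolar type 2 genes had a median of -0.20 with 0 of 14 (camera adjusted p = 0.00141, and adjusted p = 0.921 with an estimated correlation). Spearman rho with exonic length was -0.23.

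Libraries were regrouped in other splits, and the genes past the threshold were counted in a fit of the compared groups alone. For carbon black against sham at day 1 the real grouping gave 7 genes, the highest other split 35, and 2 of 35 splits gave as many, so chance cannot be excluded. At day 1 the same test covered ozone against sham (2220, highest other 1), co-exposure against sham (2787, highest other 1) and co-exposure against carbon black (3696, highest other 1). Each count was reached by 1 of 35 splits, the real grouping itself. That is the smallest share possible and under 0.05, without adjustment over the comparisons. It argues against chance as the source of these counts, provided that the libraries are separate samples. Co-exposure against ozone at day 1 gave 0 with a highest other of 260, and the sham groups of both days gave 0 with a highest other of 4. With a real count of 0 all 35 splits give as many, so these say nothing. Counts from the fit of all 28 libraries were not compared with splits.

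At day 4 only 10 splits exist, too few to exclude chance. The real value and the highest other were 7 and 3 for carbon black, 4063 and 0 for ozone, 3175 and 2 for co-exposure, and 2373 and 0 for co-exposure against carbon black, each with 1 split as large. They were 0 and 0 for co-exposure against ozone, with all 10 splits as large.

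For the interactions and day differences 100 splits were drawn. They regroup libraries of different exposures, so they say nothing on whether chance can be excluded. A smaller number had been drawn first, and its results were seen before the number was raised. The day 1 interaction gave 898 with a highest other of 2049, and 5 of 100 splits gave as many. The ozone and co-exposure day differences gave 1125 and 1256 with a highest other of 3090 and 5524, and 7 and 8 of 100 gave as many. Splits with several times the real count point to a structure of the samples, which could be the exposure effects themselves and was not tested. The day 4 interaction gave 0 with a highest other of 180, so all 100 splits gave as many. The carbon black day difference gave 2 with a highest other of 2, and 4 of 100 splits gave as many, a share under 0.05 that the first, smaller draw did not reach.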
